A study of Mus musculus with 2 samples.

How the data were processed

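Splenic T-B conjugates of K/BxN Th17 fate-mapping mice were sorted by the authors, per the labels' protocols, from cells enriched on CD4 microbeads. The gate took CD4, TCRβ, CXCR5, PD-1 and CD19 positive, CD25 negative events that were either ZsGreen-positive or ZsGreen-negative. The conjugates were pulled apart with EDTA and loaded on the 10x Genomics droplet system. The K/BxN strain carries the KRN T cell receptor transgene and develops autoimmune arthritis, and ZsGreen is the label of the Th17 fate-mapping allele; the promoter that drives it is not given in the sources used here. The labels call the ZsGreen-negative library a control, and this name was read from the design text together with the deposited column that names each cell's sort. There were 2 libraries, 1 per group, and the number of mice behind each was not given in the sources used here.

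The authors deposited 1 table per library with a row for each cell and 15241 gene columns, the same in both. The gene values deposited by the authors are estimated counts, not scaled, of which 0.0657% in the ZsGreen-negative and 0.0591% in the ZsGreen-positive library were not whole among values above 0. The number of expressed genes per cell is a count in the deposited tables, and the mitochondrial and ribosomal shares are a percent of each cell's total, per the file headers. Cell Ranger, Partek and DESeq2 and the mouse build mm39 are named per the submitters' processing notes, without versions or roles. The lowest totals per cell were 401 and 402 counts, the highest gene numbers 3943 and 3976, and the highest mitochondrial shares 4.98% and 5.01%. No filter behind these values is given in the sources used here. An upper limit on genes per cell, if one was set, can remove conjugates that stayed together. No coordinates are printed, because the annotation at hand is of another build than the authors'.

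Cells with at least 200 genes and at most 10% mitochondrial counts were kept, which left out 1 cell of the ZsGreen-positive library. A deposited column named Is cell read false for 144 of 1233 ZsGreen-negative and 972 of 4880 ZsGreen-positive rows. This column was not used as a filter, and no setting left these rows out. Both libraries were clustered together with scanpy 1.11.5. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without receptor segments, mitochondrial and ribosomal protein genes gave 30 principal components. A graph of 15 neighbours was divided by the Leiden method at resolution 1, with igraph 0.11.9. A cluster was T-like or B-like where over 50% of its cells held at least 2 of 7 identity genes of that class. Names came from markers fixed beforehand, with at least 3 markers raised by at least 2-fold. A further rule was set after the clusters were seen. It moved a T-like cluster to the other cells where its 10 leading genes held more markers of a B cell, plasma cell, myeloid, NK, erythroid or platelet list than of the T cell lists; the follicular B list was not among these. It moved cluster 8, led by immunoglobulin RNA, with 3.73% and 5.43% of the cells of the ZsGreen-negative and ZsGreen-positive libraries, and the NK cell-like cluster 13, with 1.87% and 2.42%; 69.8% and 83.7% of the cells of clusters 8 and 13 held T cell identity genes. Cluster 5 was kept as T-like. Its leading genes include Ccr7 and Sell, which stood in the follicular B list and also mark naive T cells; 97.2% of its cells held T cell identity genes and 0% B cell identity genes. A cell with at least 2 identity genes of both classes was called mixed and kept out of both. Scrublet called 9 of 6112 cells doublets, or 0.147%, and is taken not to have worked; the mixed-cell rule stood in for it.

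Counts were summed over the cells of a class in each library, rounded to whole numbers after summing, and expressed per 1000000 counts of the class total (CPM). With 1 library per group no test was possible. Sums carry exact Poisson, shares exact Clopper-Pearson and ratios exact conditional binomial 95% intervals. All of these cover counting error only and leave out the spread between cells and between mice. A count of 0 was given a floor of 3 counts. Genes with at least 30 counts over both libraries entered the lists, and each list median is set beside 10000 random lists of equal size matched in 20 expression bins. The median interval used to compare settings came from 500 Poisson draws. Named genes needed at least 30 counts, 50 CPM in a library and an interval excluding 1, without receptor, mitochondrial, ribosomal, sex-linked and uncharacterised genes and without genes whose level was under 10% of that in the other class. The 12 highest and 12 lowest ratios qualified, with list members of largest ratio and defining genes beside them. This rule, the lists, the markers and the comparisons were fixed before the data were examined. Il23r lies outside the rule and was chosen after its values were seen. For shares of cells with a count, cells were also thinned to 1228 counts.

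On simulated counts for the T-like comparison of 11474 genes, intervals held the true ratio for 95.5% of genes, and 97% of 100 genes raised 2-fold and 100% of 100 genes raised 4-fold were recovered. For the B-like comparison of 661 genes these shares were 97.4%, 66% and 100%. The simulated counts were Poisson draws, the model behind the intervals, so a coverage near 95% was set in advance. They held no spread between cells or mice, so these shares do not show how the intervals perform on real cells. Alternatives covered cell filters, doublets, class rules, cluster resolution, scaling, weighting of cells, count minimums and thinning, and others were added after the data were seen. A gene value under an alternative needed at least 30 counts in that setting, a rule set after lower counts had given values at the floor. Equal weighting of cells used the unweighted counts for this rule. List medians of an alternative rest on the members that pass its count minimum. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.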

Results

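Single-cell transcriptomes were measured from dissociated conjugates of B cells with follicular helper T (Tfh) cells sorted by the presence or absence of ZsGreen, the fluorescent label of the Th17 fate-mapping mice. The question is how Tfh cells with this label, and their B cell partners, differ from those without it. The comparisons below are of all T-like and all B-like cells. Of the T-like clusters, only clusters 2 and 6 were named Tfh-like. Cluster 2 held 14.3% of ZsGreen-negative and 15.8% of ZsGreen-positive T-like cells, and cluster 6 held 14.8% and 8.04%. The ZsGreen-negative library held 1233 cells and 5084459 counts, with a median of 3640 counts and 1681 genes per cell. The ZsGreen-positive library held 4880 cells and 17035237 counts, with medians of 2937 counts and 1361 genes. The deposited Is cell column read false for 144 ZsGreen-negative and 972 ZsGreen-positive rows, which are counted as cells here. Each group was 1 library, so no difference below has a replicate check, and all intervals are 95% intervals of counting error.

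As deposited, both libraries were mainly T-like cells, and few B-like cells were present in either. T-like cells made up 82.2% of the ZsGreen-negative library (79.9 to 84.3%; 1013 cells) and 77.5% of the ZsGreen-positive library (76.3 to 78.7%; 3782 cells). B-like cells made up 1.38% (0.805 to 2.20%; 17 cells) and 1.19% (0.904 to 1.53%; 58 cells). Cells with RNA of both lineages made up 0.162% (0.0196 to 0.585%) and 0.225% (0.113 to 0.403%). Other cells made up 16.3% (14.3 to 18.5%) and 21.1% (19.9 to 22.2%), and included dendritic cell-like, neutrophil-like, NK cell-like and monocyte-like clusters. The gate took CD19-positive events, yet few B-like cells were present. The deposited columns B cell, CXCR4 B, CXCR4 GCB, CXCR4+/- GCB and GCB held a value for 0 cells of either library. Whether B cells were removed before deposit is not given in the sources used here. The sort and any cell filter applied before deposit can both set these shares.

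**Figure D1:**
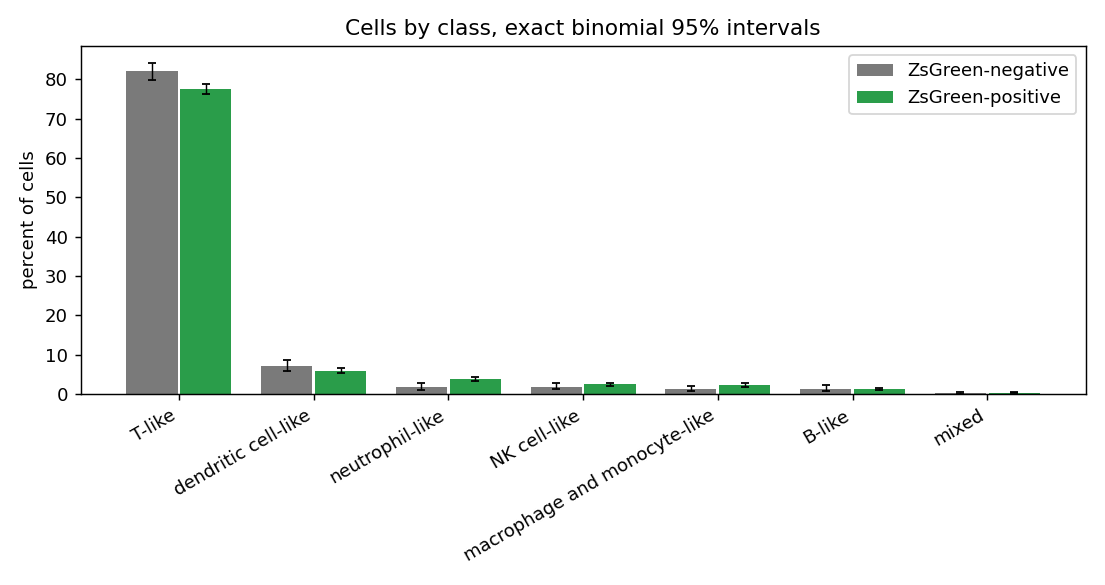
Percent of the cells of each library (vertical axis) by class (horizontal axis), in grey for the ZsGreen-negative and green for the ZsGreen-positive library, with exact binomial 95% intervals. T-like cells made up 82.2% and 77.5%, and B-like cells 1.38% and 1.19%, and unnamed clusters are not drawn.

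In T-like cells, the Th17 program was higher in the ZsGreen-positive library. Of 23 measured genes of this list, 16 were at least 1.5-fold higher, 0 were at least 1.5-fold lower and 7 lay between. The list median of the log2 ratio was 1.14, above all 10000 random lists. Il17a, the cytokine that defines Th17 cells, had 8 and 146 counts, a ratio of 5.92 (2.92 to 13.96), and Il17f had 2 and 144 counts, a ratio of 23.3 (6.35 to 195). Rorc, which encodes the Th17 regulator RORγt, had a ratio of 2.20 (1.59 to 3.12). The chemokine receptor gene Ccr6 was 3.79-fold higher (2.92 to 5.01) and the interleukin-23 receptor gene Il23r 3.17-fold higher (2.11 to 4.94).

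These transcripts were rare per cell. Il17a was detected in 0.197% of ZsGreen-negative T-like cells (0.0239 to 0.711%) and 0.687% of ZsGreen-positive ones (0.450 to 1.01%), at median depths of 3833 and 3031 counts. The 146 Il17a counts came from 26 cells and the 144 Il17f counts from 47 cells, so counting intervals are too narrow for these genes. Rorc was detected in 2.96% (2.01 to 4.20%) and 5.10% (4.42 to 5.85%) of T-like cells. After thinning to 1228 counts, which left out 44 and 299 cells, Rorc was detected in 1.14% (0.568 to 2.02%) and 1.87% (1.44 to 2.37%), and these intervals overlap. Ccr6 was detected in 3.95% (2.84 to 5.34%) and 10.6% (9.64 to 11.6%), and after thinning in 1.44% (0.792 to 2.41%) and 4.68% (4.002 to 5.43%). In dendritic, neutrophil and monocyte-like cells, at median depths of 2559 and 2340 counts, Il17a was detected in 0 of 125 and 0 of 577 cells, Rorc in 0 and 2 cells, and Ccr6 in 8% (3.90 to 14.2%) and 3.12% (1.86 to 4.89%). The Ccr6 intervals of ZsGreen-negative T-like cells and of these other cells in either library overlap.

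The authors' deposited table places each of 1032 ZsGreen-negative and 3872 ZsGreen-positive cells in 1 of 5 groups. The Rorc+T group held 1.26% (0.672 to 2.14%) and 1.32% (0.982 to 1.73%) of these cells, Rora+T 29.8% (27.1 to 32.7%) and 30.2% (28.8 to 31.7%), IL17a+T 0.194% (0.0235 to 0.698%) and 0.387% (0.217 to 0.638%), and IL17f+T 0.194% (0.0235 to 0.698%) and 1.24% (0.915 to 1.64%). The intervals of the first 3 groups overlap. The largest group, named exTh17Tfh liked, held 68.5% (65.6 to 71.3%) and 66.8% (65.3 to 68.3%), and these intervals overlap too. Of the gated cells with Rorc RNA, 16 of 29 and 141 of 192 had been placed in another group, and Rorc was detected in 2.81% (1.89 to 4.01%) and 4.96% (4.30 to 5.69%) of all gated cells.

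The Tfh program was lower in the ZsGreen-positive library by a smaller amount. Of 29 measured genes, 0 were at least 1.5-fold higher, 7 at least 1.5-fold lower and 22 between, and the median log2 ratio of -0.35 lay below all 10000 random lists. In the authors' gate of CD4 T cells without Foxp3, 0 of 28 genes were at least 1.5-fold lower. Cxcr5, the follicle homing receptor gene, had a ratio of 0.588 (0.504 to 0.687), Il21, a cytokine that helps B cells, 0.602 (0.508 to 0.716), and Pdcd1, which encodes PD-1, 0.667 (0.612 to 0.726). Cxcr5 was detected in 17.6% of ZsGreen-negative and 9.78% of ZsGreen-positive T-like cells, and Pdcd1 in 33.5% and 23.2%. Median depths were 3833 and 3031 counts. The T-like class also held Treg-like and unnamed clusters, so the ratios of this paragraph are not those of Tfh-like cells alone. Sostdc1 had the lowest ratio of the Tfh list, 0.408 (0.331 to 0.504). Bcl6, the Tfh lineage regulator, had a ratio of 0.802 (0.673 to 0.958), Icos 0.781 (0.717 to 0.853) and Cd40lg, the CD40 ligand gene, 0.817 (0.746 to 0.895). On the T side of the T-B contact, 2 of 19 genes were at least 1.5-fold lower and 0 higher, with a median of -0.29 at percentile 0.02 of random lists, and Cd200 at 0.592 (0.529 to 0.663).

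Immediate early genes were lower in the ZsGreen-positive library. Of 22 genes, 11 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.54, below all 10000 random lists. Dusp1, a phosphatase gene, had a ratio of 0.402 (0.380 to 0.424), Nr4a1, which encodes Nur77 and responds to T cell receptor signals, 0.479 (0.448 to 0.513), the AP-1 gene Junb 0.494 (0.481 to 0.508), and Tnfaip3, an inhibitor of NF-kB signalling, 0.477 (0.447 to 0.509). The heat shock list had a median of -0.34, at percentile 0.12, with 3 of 11 genes at least 1.5-fold lower and Hspa1b at 0.402 (0.360 to 0.449). The same immediate early list had a median of -0.48 in dendritic cell-like cells. In the authors' deposited table, 42.8% of the 652 gated ZsGreen-negative cells were Nur77-positive (39.0 to 46.7%), against 28.8% of 2150 ZsGreen-positive cells (26.9 to 30.8%). In all 2802 gated cells this gate equalled detection of Nr4a1, so it depends on depth. With cells thinned to 1228 counts, Nr4a1 was detected in 23.3% (20.7 to 26.1%) and 14.6% (13.5 to 15.8%) of T-like cells, and in 17.6% (10.4 to 27.0%) and 15.3% (11.97 to 19.2%) of dendritic, neutrophil and monocyte-like cells.

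**Figure D2:**
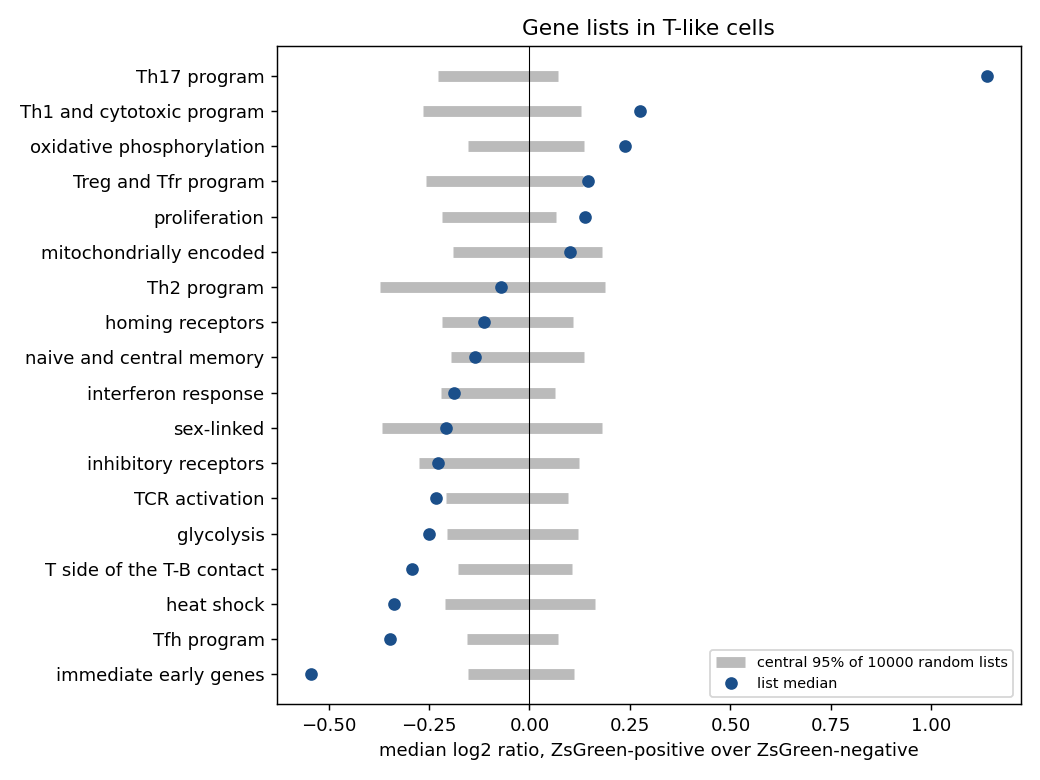
Median log2 ratio of ZsGreen-positive over ZsGreen-negative T-like cells (horizontal axis) for each gene list (vertical axis), as points, with the central 95% of 10000 random lists as grey bars. The Th17 program stood highest at 1.14 and immediate early genes lowest at -0.54.

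The other T cell lists stood nearer to 0. Oxidative phosphorylation had a median of 0.24 (percentile 99.96), with 0 of 18 genes beyond 1.5-fold. The same list had a median of 0.32 in dendritic, neutrophil and monocyte-like cells, above its random range, with 4 of 18 genes at least 1.5-fold higher, and of 0.19, inside its random range, in dendritic cell-like cells alone. Ndufs5 had a ratio of 1.39 (1.23 to 1.58), and Cox4i1 1.34 (1.29 to 1.40). Glycolysis had a median of -0.25 (percentile 0.89), with 4 of 14 genes at least 1.5-fold lower and Gapdh at 0.426 (0.411 to 0.441). The Th1 and cytotoxic list had a median of 0.27 (percentile 99.96), with 5 of 16 genes at least 1.5-fold higher and 2 lower, Gzma at 4.96 (2.89 to 9.22) and Ifng at 0.343 (0.265 to 0.444), and its median was -0.12 when each cell had equal weight. Proliferation genes had a median of 0.14 (percentile 99.91), with 1 of 20 genes beyond 1.5-fold on each side, Mki67 at 1.23 (1.07 to 1.42) and Tuba1b at 0.508 (0.477 to 0.540); Mki67 lay at a log2 ratio of -0.16 with equal weights. The Treg and Tfr list had a median of 0.15 (percentile 98.2), with 1 of 13 genes at least 1.5-fold higher and 3 lower, Foxp3 at 0.992 (0.870 to 1.14) and Ctla4 at 0.614 (0.566 to 0.666). TCR activation genes had a median of -0.23 (percentile 1.10), with 4 of 16 genes at least 1.5-fold lower, Il2 at 0.379 (0.273 to 0.528) and Bhlhe40 at 0.538 (0.483 to 0.599).

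Several of these medians depended on the cells included. Of 9 settings that left out, kept or weighted clusters or used the authors' gate, all chosen after the data were seen, the median lay inside its random range in 8 for Treg and Tfr, 4 for TCR activation, 4 for Th1 and cytotoxic, 3 for proliferation, 3 for glycolysis, 2 for T-B contact and 1 each for oxidative phosphorylation, heat shock, Th17 and immediate early genes, and in 0 for the Tfh program. Without cluster 4 the medians were -0.060 for proliferation, 0.018 for Treg and Tfr and -0.16 for TCR activation, and the log2 ratio of Il2 was 0.0057. With clusters weighted to the ZsGreen-negative shares, the Treg and Tfr median was 0.023, that of TCR activation -0.11, and that of immediate early genes -0.28, with 4 of 22 genes at least 1.5-fold lower.

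Medians of inhibitory receptors (-0.23), interferon response (-0.19), naive and central memory (-0.14), homing receptors (-0.11), Th2 (-0.072), sex-linked (-0.21) and mitochondrially encoded genes (0.10) lay inside their random ranges. In the 9 other settings chosen after the data were seen, the median lay outside its range in 3 for inhibitory receptors, 2 for interferon response, 3 for naive and central memory, 1 for homing receptors, 2 for mitochondrially encoded and 0 for sex-linked genes, and in 0 for Th2 where it was measured. The naive and central memory median was -0.33 without cluster 5 and -0.29 without cluster 4. In the main setting, in the order of the medians above, 0, 0, 1, 3, 1, 0 and 0 genes were at least 1.5-fold higher and 4, 3, 3, 3, 1, 0 and 0 lower, of 11, 21, 15, 19, 7, 5 and 13 measured. Lag3 had a ratio of 0.488 (0.416 to 0.572), Irf7 0.601 (0.517 to 0.700), Ccr7 0.618 (0.570 to 0.669), Igfbp4 0.654 (0.607 to 0.704), Areg 1.72 (1.30 to 2.30) and Ccr9 3.30 (1.43 to 9.33).

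Among all genes of T-like cells, the highest ratios by the fixed rule were those of Tmem176a at 5.01 (3.72 to 6.91), Tmem176b at 4.36 (3.36 to 5.75) and Ccr6. St6galnac3 had a ratio of 2.07 (1.86 to 2.30), and Nrgn, Nebl and Plcb4 had ratios of 1.92, 1.86 and 1.66. The small calcium-binding protein genes S100a4 and S100a6 had ratios of 1.97 (1.86 to 2.08) and 1.75 (1.68 to 1.82), and the galectin genes Lgals3 and Lgals1 1.85 (1.59 to 2.17) and 1.70 (1.65 to 1.76). Some of these genes were also high in the other cells of both libraries, where Tmem176a stood at 201 and 154 counts per 1000000 (CPM) and Lgals3 at 484 and 690. In those cells S100a4 (437 and 670), S100a6 (1166 and 1581) and Nrgn (6.89 and 27.9) were also higher in the ZsGreen-positive library. Ccr6 (17.9 and 9.21) and Plcb4 (30.3 and 19.8) were lower there. The lowest ratios were those of Hist1h2ap at 0.299 (0.268 to 0.333), Csrnp1 at 0.305 (0.265 to 0.350), Ccnb1ip1 at 0.318, Pim3 at 0.324, Socs3 at 0.343 and Rgs16 at 0.368. Fgfr2 had a ratio of 0.400 (0.377 to 0.423) and stood at 681 and 258 CPM in the other cells. Ccnb1ip1 (85.4 and 34.9), Socs3 (68.9 and 38.8) and Csrnp1 (40.0 and 25.1) were also lower there in the ZsGreen-positive library. Pim3 (15.2 and 14.5) and Rgs16 (8.27 and 7.81) differed little there, and Hist1h2ap (52.4 and 65.0) went the other way. The other cells include clusters 8 and 13, where 69.8% and 83.7% of cells held T cell identity genes.

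**Figure D3:**
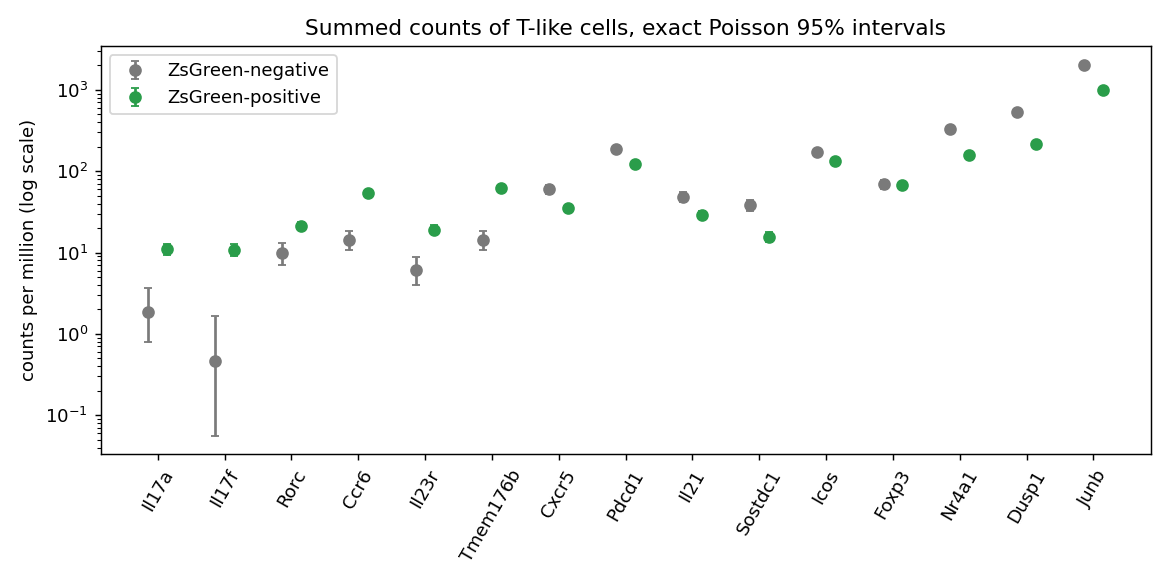
Counts per 1000000 counts (CPM) of T-like cells on a log scale (vertical axis) for 15 genes (horizontal axis), in grey for the ZsGreen-negative and green for the ZsGreen-positive library, with exact Poisson 95% intervals. Il17a stood at 1.86 and 10.98 CPM, and Cxcr5 at 60.1 and 35.3.

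The differences were not shared evenly by the T-like clusters. Clusters were made from variable genes, which can include genes of these programs. Cells high in a program can then form their own cluster, which leaves less difference in the others. The medians below, within or without a cluster, therefore do not show where a difference arose. In the Tfh-like cluster 2 alone, chosen after the data were seen, the medians were -0.062 for the 8 measured Th17 genes, -0.14 for the Tfh program and -0.034 for immediate early genes. Nr4a1 and Tnfaip3 were higher there, at log2 ratios of 0.24 and 0.16. The Th17 and immediate early medians lay inside their random ranges, and that of the Tfh program at percentile 1.495. Cluster 5 carries 2 leading genes of the follicular B marker list, and without it the Th17, Tfh and immediate early medians were 1.12, -0.36 and -0.52. Without cluster 9, whose leading genes include Tmem176a, Ccr6 and Rorc, the Th17 median was 0.27. Clusters 9 and 4 are defined by the genes that differ, so their shares are given as values only: cluster 9 held 1.48% (0.831 to 2.43%) and 7.32% (6.51 to 8.20%) of T-like cells, and cluster 4, led by Tnfaip3, Csrnp1 and Dusp1, 20.9% (18.5 to 23.6%) and 8.75% (7.87 to 9.70%). After clustering without 108 genes of these programs, the best match of cluster 9 held 9.24% and 18.0%, and took in 259 of the 293 cells of cluster 9 (88.4%), which made up 32.6% of its own cells. The best match of cluster 4 held 20.7% and 15.6%, took in 226 of the 543 cells of cluster 4 (41.6%), and these made up 27.6% of its own cells. The Treg-like cluster held 11.9% (10.0 to 14.1%) and 14.8% (13.7 to 15.98%), the cycling-like cluster 3.95% (2.84 to 5.34%) and 3.07% (2.54 to 3.67%), and the Tfh-like cluster 2 14.3% (12.2 to 16.6%) and 15.8% (14.6 to 17.0%).

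Cells with ribosomal protein RNA under 5% made up 15.4% of ZsGreen-negative T-like cells (13.2 to 17.8%) and 8.59% of ZsGreen-positive ones (7.72 to 9.53%). Cluster 6, a Tfh-like cluster with a median ribosomal share of 2.37%, held 14.8% (12.7 to 17.1%) and 8.04% (7.19 to 8.95%) of T-like cells.

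B-like cells were few, 17 and 58, and formed 1 cluster, named marginal zone B-like by the fixed rule. Its 10 leading genes held 6 general B cell markers and 1 marginal zone marker. Markers were scored against all other cells, so the name does not tell B cell subsets apart. The summed counts of the B-like cells were 38101 and 93150. Of the ZsGreen-negative ones, 82.4% (56.6 to 96.2%) had a ribosomal share under 5%, against 36.2% of the ZsGreen-positive ones (24.0 to 49.9%). The antigen presentation list had a median log2 ratio of 0.13 over 9 genes, inside its random range, with Cd74, the class II invariant chain gene, at 1.37 (1.22 to 1.53), H2-DMa at 2.21 (0.838 to 7.34) and Ifi30 at 2.94 (1.15 to 9.61). Without the low-ribosomal cells its median was -0.21, and the log2 ratio of Cd74 was also -0.21, from 3 ZsGreen-negative and 37 ZsGreen-positive cells. Cd86, a costimulatory ligand gene, had 27 and 14 counts, a ratio of 0.212 (0.103 to 0.419). Vpreb3 had 2 and 55 counts, a ratio of 11.2 (2.97 to 95.2). Cox6c had 1 and 32 counts, a ratio of 13.1 (2.19 to 533), and Ptma had a ratio of 4.27 (2.55 to 7.64). The ratios of Cd86, Vpreb3, Cox6c and Ptma rest on all B-like cells. They cannot be told apart from the uneven share of low-ribosomal cells.

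Other B-like lists gave medians of -0.033 for naive follicular, -0.66 for marginal zone, -1.08 for memory and age-associated, -0.53 for CD40 and NF-kB activation, 0.16 for immediate early, 0.59 for oxidative phosphorylation, -0.53 for heat shock and -0.31 for mitochondrially encoded genes, each over 12 genes or fewer. None of these medians lay outside its random range, and that of oxidative phosphorylation lay at the upper end. The memory and CD40 lists rest on 3 genes each. These medians, too, cannot be told apart from the uneven share of low-ribosomal cells. Germinal centre, plasma cell, T-B contact, heavy constant, interferon, proliferation, glycolysis and sex-linked lists had fewer than 3 measured genes. Median-ratio scaling moved all B-like log2 values by 0.29.

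Heavy chain constant RNA of B-like cells was mainly unswitched. Ighm and Ighd made up 46 of 46 counts in the ZsGreen-negative library (92.3 to 100%) and 92.4% of 144 counts in the ZsGreen-positive library (86.7 to 96.1%). Each switched isotype had 0 counts in the ZsGreen-negative library, which allows a share of up to 7.71%. In the ZsGreen-positive library Igha had 6 counts, Ighg1 4 and Ighg2c 1. Ighm RNA was also detected in 36.2% and 31.7% of T-like cells, so a part of these counts due to free RNA cannot be told apart.

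Trbv19, the V gene of the KRN transgene's beta chain, made up 67.8% of Trbv counts in ZsGreen-negative T-like cells (67.1 to 68.5%) and 70.6% in ZsGreen-positive ones (70.2 to 71.0%). By leading Trbv gene, 77.2% (74.5 to 79.9%) and 77.3% (75.9 to 78.7%) of cells were Trbv19 cells. Trav6 members made up 46.8% (45.7 to 47.9%) and 51.1% (50.4 to 51.8%) of Trav counts.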

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

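Tests in dendritic cell-like and other non-T cells and those without clusters 9 and 4 were chosen after the result was seen, and so was the setting that weights clusters, which was added after the data were seen; thinning was planned.

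Clusters named for cell types other than T and B cells appeared in both libraries, outside the comparisons made. Dendritic cell-like cells made up 7.14% of the ZsGreen-negative and 5.88% of the ZsGreen-positive library, neutrophil-like cells 1.78% and 3.69%, NK cell-like cells 1.87% and 2.42%, and macrophage and monocyte-like cells 1.22% and 2.25%. They were flagged for lying above the limit that a count of 0 allows, which says only that such clusters were there. T cell identity genes were held by 83.7% of the NK cell-like cells, which left the T-like class by a rule set after the clusters were seen.

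The Th17 program was higher in ZsGreen-positive T-like cells. Without cluster 9 the median was 0.27, above the random range that ends at 0.10, so T-like cells outside this cluster also stood higher. Clustering can leave like cells in other clusters, and free RNA of cluster 9 would remain. The median without it therefore does not decide on cluster 9 as the whole source. Cluster 9 is led by genes of this list, so the fall of the median without it does not show a part due to that cluster. Free RNA as the source of the whole rise is argued against. It would need each gene to stand, in ZsGreen-positive dendritic, neutrophil and monocyte-like cells, at least as high as its rise in T-like cells. Of 17 genes whose rise had a lower limit above 0, the upper limit in those cells lay below it for 11. Il17a had 0 counts and Rorc 2 there, against rises of 9.12 and 11.7 CPM. These limits cover counting error only and are too narrow for Il17a and Il17f, which are among the 11. Over all 23 measured genes 11 is no majority, which the test first asked for; the genes without such a rise were left out after that outcome was seen, because they could not have met it. For the other 6 genes free RNA cannot be told apart from a rise within the cells, since their upper limits in those cells lay above the lower limit of the rise; Tmem176a and Tmem176b stood at 260 and 420 CPM there. Values that go with more free RNA in the ZsGreen-positive library are those of S100a9, detected in 1.58% and 12.2% of T-like cells, of Igkc, in 3.55% and 12.2%, and of Jchain, in 1.88% and 6.95%, while Ighm went the other way, with 36.2% and 31.7%, and Cd79a stood at 0.691% and 0.767%. In the pooled non-T cells the Th17, Treg and Tfr, and Tfh medians were 0.055, 0.92 and 0.17, of which only that of Treg and Tfr lay outside its random range, and in dendritic cell-like cells alone they were -0.27, 0.30 and -0.023, all inside. Genes at least 1.5-fold higher and lower in the pooled cells were 8 and 0 of 21 for Tfh and 5 and 0 of 15 for T-B contact, and in dendritic cell-like cells 4 and 2 of 16, and 2 and 1 of 9. The libraries were sorted on a Th17 fate-mapping label, so the Th17 list may not be independent of the sort itself. The Th17 history that the ZsGreen label stands for remains a possible explanation that 1 library per group leaves untested.

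The Tfh program was lower in ZsGreen-positive T-like cells. Different shares of the clusters would bring the weighted median into the random range. It was -0.20 against a lower end of -0.12, so the shares of these clusters are argued against as the whole source. A part due to them was not tested. Weighting leaves different mixes of cells within a cluster as they were, so it does not decide on shares of cell types in general. Cluster 4 as the sole source is argued against by a median of -0.34 without it. The thinned median was -0.42, so the shift remained with equal counts per cell. Summed CPM are scaled by the class total, so thinning could hardly have removed the shift and does not decide on depth. A biological difference between the sorted populations stays open and untested.

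Immediate early genes were lower in ZsGreen-positive T-like cells. The thinned median was -0.63, so the shift remained with equal counts per cell. Summed CPM are scaled by the class total, so thinning could hardly have removed the shift and does not decide on depth. Different shares of these clusters as the whole source are argued against by a weighted median of -0.28 against a random range that starts at -0.12. Different mixes of cells within a cluster stay after weighting and were not tested. Cluster 4 is led by genes of this list, so what its weighting takes away does not show a part due to shares. Handling or library preparation acting on all cell types predicts the same shift outside T cells, and the median in dendritic cell-like cells was -0.48, below a random range that starts at -0.21. For this list, the value goes with a difference between the libraries as a whole, from 88 and 287 dendritic cell-like cells. In the pooled non-T cells its median was -0.37, also below its random range. The heat shock list, lower in T-like cells, did not share this shift. Its median was -0.0055 in dendritic cell-like and -0.18 in the pooled cells, both inside their random ranges. Some immediate early values also did not share it. In the Tfh-like cluster 2 alone the list median was -0.034, inside its random range, with Nr4a1 at a log2 ratio of 0.24. Clusters can form from genes of this list, so the cluster 2 value does not decide on handling. Nr4a1 was detected in 32.0% (23.9 to 40.9%) and 30.7% (26.9 to 34.6%) of the pooled cells. A difference in T cell receptor signalling between the sorted populations stays open and untested.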

How the results depend on the processing

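No paired analysis was possible because each group is 1 library. Settings that keep or drop clusters, the authors' gate, cluster weights, the ribosomal share and clustering without program genes were chosen after seeing the data. The Th17 program stayed above 0 under every setting but cluster 2 alone, and the Tfh and immediate early medians stayed below 0 under all settings. The cause of each shift was not tested. The mitochondrial limit of 5% removed 1 further cell, so its shifts come with the new clustering. Leaving out Scrublet doublets removed 8 ZsGreen-negative cells and 1 ZsGreen-positive cell, so those shifts come mainly with the new clustering too. The intervals of cluster shares do not cover this spread between clusterings. Of the other values, 2567 for single genes and further lists and 127 for shares and leading lists stayed inside their intervals, and 283 for single genes and further lists lay outside them without a called value changing sign.

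For the ZsGreen-negative and ZsGreen-positive T-like shares, the 5% mitochondrial limit gave 85.5% and 82.0%, resolution 0.5 gave 86.0% and 82.5%, resolution 2 gave 84.3% and 82.0%, thinning gave 84.8% and 81.1%, and mixed cells defined by 1 gene of each class gave 78.1% and 74.3%. The ZsGreen-positive T-like share was 72.0% with at least 500 genes, 80.1% without Scrublet doublets and 80.0% by identity genes alone. Mixed shares were 5.35% and 4.28% with 1 gene of each class, 0% and 0.0920% after thinning, and 0% in the ZsGreen-negative library with 3 genes; the ZsGreen-positive B-like share was 0.902% with 1 gene. With at least 500 genes, cluster 9 held 10.0% of ZsGreen-positive and cluster 4 17.4% of ZsGreen-negative T-like cells, and the ZsGreen-positive Trbv19 share was 72.0%. Without Scrublet doublets cluster 4 held 15.4% and 7.17%. Clustering without program genes gave 9.24% and 18.0% for cluster 9 and 20.7% and 15.6% for cluster 4. Identity genes alone gave an Ighm and Ighd share of 99.1% in the ZsGreen-positive library.

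For the Tfh, Th17 and immediate early medians, thinning gave -0.42, 0.85 and -0.63, cluster 2 alone -0.14, -0.062 and -0.034, the authors' gate -0.26, 1.39 and -0.62, and cluster weights -0.20, 0.48 and -0.28. Tfh genes at least 1.5-fold lower numbered 7 in the main setting, 4 after thinning, 2 in cluster 2 alone, 0 in the authors' gate and 3 under cluster weights. Th17 genes at least 1.5-fold higher numbered 16 in the main setting, 1 of 8 measured in cluster 2 alone (with 1 lower, against 0), 10 without cluster 9 and 10 under cluster weights. Immediate early genes at least 1.5-fold lower numbered 11 in the main setting, 2 in cluster 2 alone and 4 under cluster weights. Median-ratio scaling gave -0.28 for Tfh and -0.48 for immediate early genes. Without cluster 9 the Th17 median was 0.27 and Cxcr6 -0.10, and without cluster 4 the immediate early median was -0.39 and Il2 0.0057. Cxcr6 was -0.016 under cluster weights, and Uty 0.13 without cluster 6. Equal weights gave -0.12 for the Th1 list, -0.23 for Cdk1, -0.16 for Mki67, -0.18 for Ube2c and, in B-like cells, 0.22 for Junb. In cluster 2 alone, log2 ratios were -1.51 for Cxcr6, 0.52 for Hist1h3e, 0.011 for Icos, -0.30 for Lysmd2, -0.85 for Mki67, 0.24 for Nr4a1, -0.059 for Nrgn, 0.057 for Sostdc1, 0.16 for Tnfaip3 and 0.90 for Uty. In the authors' gate the interferon median was 0.039, Ifit1 0.78, Ifit3 1.30 and Mki67 -0.37.

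In B-like cells the antigen presentation median was 0.75 after thinning, -0.22 by identity genes alone and -0.21 without low-ribosomal cells. Identity genes alone gave 0.15 for the memory list, -0.18 for Cd74 and 0.13 for Hspa8. Without low-ribosomal cells oxidative phosphorylation was -0.14, mitochondrially encoded genes 0.10, Cd74 -0.21 and Cr2 0.34. Few cells limit each of these: 15 and 52 after thinning, 21 and 69 by identity genes alone, 3 and 37 without low-ribosomal cells, and 17 and 58 otherwise.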

Other observations

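Rarer populations appeared besides those compared. Cluster 7, led by Sox5, Sox4 and Trdc, held 6.81% of ZsGreen-negative (5.34 to 8.54%) and 8.12% of ZsGreen-positive T-like cells (7.27 to 9.03%). Cluster 19, led by Ifit3, Ifit1 and Isg15, held 0.494% and 0.529%. Cluster 18, led by the neutrophil granule genes Camp, Ngp and Ltf, held 0.487% and 0.963% of all cells, and cluster 20, led by Mcpt8, Cpa3 and Gata2, held 0.0811% and 0.430%.

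Ighm RNA was detected in 36.2% of ZsGreen-negative T-like cells (33.3 to 39.3%) and 31.7% of ZsGreen-positive ones (30.2 to 33.2%), beside 25.6% and 30.7% of dendritic, neutrophil and monocyte-like cells, at median depths of 3833, 3031, 2559 and 2340 counts. Igkc was detected in 3.55% (2.501 to 4.89%) and 12.2% (11.2 to 13.3%) of T-like cells and in 5.60% and 12.7% of those other cells. S100a9, a neutrophil gene, was detected in 1.58% (0.905 to 2.55%) and 12.2% (11.1 to 13.2%) of T-like cells. After thinning, Igkc was in 1.75% and 6.29% and S100a9 in 0.619% and 5.28% of T-like cells.

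Gm42418, a locus that overlaps ribosomal RNA sequence, took 4.01% of ZsGreen-negative and 6.20% of ZsGreen-positive counts. Hexb took 0.756% and 0.389%.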
